A study of Mus musculus with 4 samples.

How the data were processed

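RNA of 4 kinds of mouse cell was measured on 4 Affymetrix oligonucleotide arrays, 1 array per kind of cell. Per the labels, the 4 samples were undifferentiated embryonic stem (ES) cells, cerebellar granule cells of postnatal day 6, cells sorted for a green fluorescent protein (GFP) reporter of HB9, and sorted Sox1-positive neural stem cells. HB9 is the protein encoded by Mnx1, a homeodomain transcription factor used as a marker of motor neurons. The labels state that the HB9 reporter ES cells were kept on mitomycin-treated mouse embryonic fibroblasts with leukemia inhibitory factor. They give Sonic hedgehog, 0.1 uM retinoic acid and 0.2 uM purmorphamine from day 5 to day 9 of differentiation. They also give day 8 for the sort. The stated end of the factors falls after the stated sort, so these days conflict and the exposure is uncertain. Total RNA was taken up in Trizol and biotin-labelled cRNA was hybridised, per the labels' protocols. The labels used here do not say how the Sox1-positive cells were obtained.

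The deposited values are linear intensities with 1 decimal, from 0.1 to 43110.3, for 45101 probe sets. The submitters' processing notes name GCRMA, without a version. The values themselves have the form of a scaled average difference and not of a log2 summary, because each array's mean over probe sets, after trimming 2% at each end, was 500.0. The step that made the deposited intensities is therefore uncertain, and scaling to a common trimmed mean forces the arrays to a common average. No detection flags were used. How the cells' total RNA content differed cannot be read from such values.

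Gene names came from the platform's annotation table, in which 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. The 64 control probe sets entered no gene. Of the 34958 probe sets, 34754 matched a gene identifier of the RefSeq annotation of GRCm38.p6, and 0 symbols changed through it. A gene was represented by its probe set with the highest mean over the 4 arrays among probe sets with 1 symbol, which gave 18193 genes, 9012 of them with at least 2 probe sets. No coordinates are given, since the array annotation names no build. Probe sets with several symbols were left out, and those without a symbol appear only in the closing section.

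Values were put on the log2 scale with no pseudocount. The low level was the mean of the 4 arrays' median log2 values, 6.30, a signal of 78.8, and values below it were set to it. A gene was called detected on an array at 1 log2 unit above the low level, a signal of 157.5. It was called higher or lower in a comparison where it was detected on the brighter array and differed by at least 2 log2 units, which is 4-fold. A fold against an array at the low level is a lower bound and is given as "at least". Where the dimmer signal lay between the low level and the detection level, both signals are given and no fold. Differences were ranked with the low level in place, so the order among bounds carries no meaning. A gene was called set apart on an array where it passed the same rule against each of the other 3 arrays. With 1 array per group there is no replicate error, so no p-value or standard error was computed and every difference is a difference between these arrays. The number of arrays limits the precision. The only measures of technical spread were the SD of the differences over 18 hybridisation control probe sets and the SD of a gene's difference over its probe sets, and neither holds biological variation.

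The 4 comparisons set the array labelled HB9-GFP+ against the ES, Sox1 neural stem cell and granule cell arrays, and the Sox1 array against the ES array. The first 3 share an array, so they are not independent. The rule of size, the 33 gene lists and 12 alternative settings were fixed before the data were examined. The lists held genes of pluripotency, motor neuron identity, motor columns, cholinergic transmission, ventral progenitors, other spinal neurons, neural stem cells, granule neurons, Purkinje cells and interneurons, pan-neuronal genes, Hox paralogs 1 to 5 and 6 to 13, the hedgehog pathway, the retinoic acid response, the cell cycle, cell cycle exit, astrocytes, oligodendrocytes, fibroblasts, vessels, blood and microglia, mesoderm and endoderm, neural crest and sensory neurons, glutamate receptors, GABA and glycine receptors, voltage-gated channels, axon guidance, trophic factors and their receptors, early response and stress genes, BAF chromatin remodelling subunits, DNA methylation regulators, glycolysis, reference genes and sex-linked genes. For each list the median log2 difference was set among 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these arrays and is not a test. List genes absent from the annotation table were not analysed here.

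Genes are named by a fixed rule. It takes the 8 largest differences in each direction per comparison, the sort genes Mnx1 and Sox1, up to 4 members of each list with the largest absolute difference in that comparison, and the 8 genes with the largest gap among those set apart on an array. Symbols that are only clone or predicted-gene names were passed over. Nanog, Sox2, Lin28a, Sall4, Trim71, Lhx3, Chat, Sparc and the genes shared by pairs of arrays are named outside this rule, after their values were seen.

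The alternatives were the mean over a gene's probe sets, probe sets without the suffixes that mark shared probes, detection margins of 0 and 2 log2 units, no floor, sizes of 1 and 3 log2 units, quantile normalization, centring on genes detected on all arrays, centring on reference genes, and pseudocounts of 1 and 16. A further 3 were added after the data were seen: centring on the hybridisation controls, centring on the reference genes without Hprt, and counting the genes set apart without the array labelled HB9-GFP+. The procedure was tested on data simulated from the ES array over 18193 genes. The added noise had the SD of the hybridisation control differences between the array labelled HB9-GFP+ and the ES array, 0.11 log2 units. It called 50 of 50 genes made 8-fold higher, 37 of 50 made 8-fold lower and 0 of 100 changed 2-fold, with 0 false calls. Genes near the low level have no room to be called lower. With noise this small beside the rule of 2 log2 units, the 0 false calls and 0 calls at 2-fold were fixed in advance. They give no error rate for the real arrays, where the probe sets of a gene had a pooled SD of 0.60 in that comparison. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.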

Results

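Gene expression was compared between undifferentiated mouse ES cells, sorted Sox1-positive neural stem cells, granule cells of the early postnatal cerebellum, and cells sorted for an HB9-GFP reporter after 8 days of differentiation towards motoneurons. Each was measured on 1 array. The number of genes detected was similar on the 4 arrays, at 9420 for ES cells, 9518 for granule cells, 9330 for the array labelled HB9-GFP+ and 9376 for Sox1 neural stem cells, of 18193 genes measured. The median signals were 86.2, 90.7, 61.9 and 79.5 in the same order. The ratio of 3' to 5' probe sets for the actin control was 4.55, 2.29, 2.77 and 5.08, and that for the Gapdh control was 1.99, 2.70, 1.37 and 3.68. Both ratios were highest on the Sox1 array, and both were higher on the ES array than on the array labelled HB9-GFP+. The rank of the granule array differed between the 2 controls. Since there was 1 array per group, no difference below has a replicate check.

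The genes used for the sorts were examined first. Sox1, a transcription factor of neural progenitors, had a signal of 2262.1 on the Sox1 array, against 193.5 on the ES array, 175.6 on the array labelled HB9-GFP+ and 437.7 on the granule array. Its other probe set was undetected on all 4 arrays, at 10.2 on the Sox1 array and 18.2 on the array labelled HB9-GFP+. Mnx1, which encodes HB9, was measured by a single probe set and was not detected on any array. Its signal was 15.9 on the array labelled HB9-GFP+, 13.7 on the Sox1 array, 6.3 on the granule array and 5.8 on the ES array. A probe set that is dark on every array cannot by itself check the label. Other genes of motor neuron identity were also examined on the array labelled HB9-GFP+, and 4 of 24 were detected there, against 5 on the ES array, 13 on the Sox1 array and 12 on the granule array. The motor neuron determinant Lhx3 was at 7.5 on the array labelled HB9-GFP+, and Chat, the enzyme that makes acetylcholine, was at 17.6. Both were below detection on all 4 arrays. Isl1, a further motor neuron determinant, was at 85.2 on the array labelled HB9-GFP+ and at 189.1 on the ES array.

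Pluripotency genes, by contrast, were detected throughout on the array labelled HB9-GFP+. All 29 measured members of that list were detected on it, with a median signal of 4954.8. The ES array also had 29 detected, with a median of 2869.7. The Sox1 array had 18 detected with a median of 286.7, and the granule array had 3 with a median of 26.7. Pou5f1, the POU factor that maintains pluripotency, was at 11188 on the array labelled HB9-GFP+ and at 9255.5 on the ES array, and Nanog was at 7700.9 and 4685.5. The values on this array therefore run against its label, and every direction below that involves it refers to the array as labelled.

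**Figure D1:**
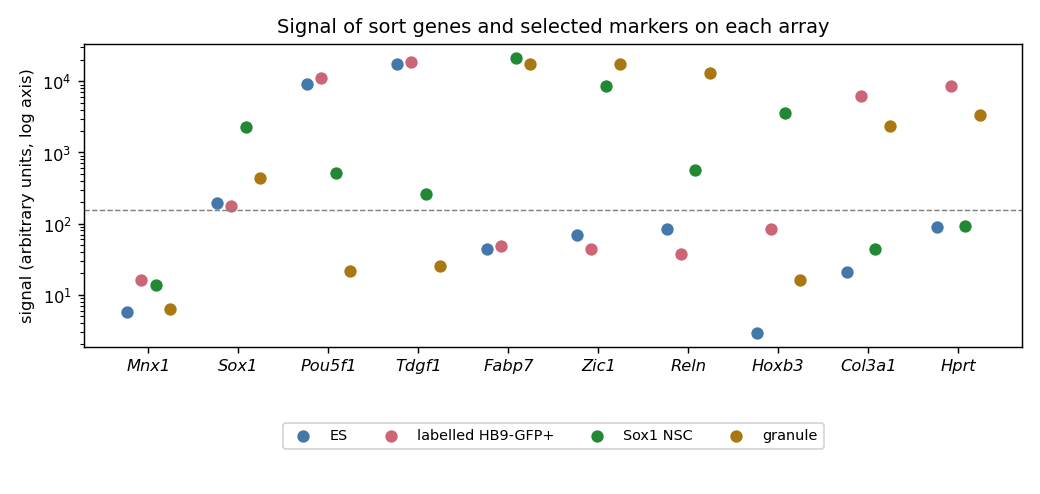
Signal (arbitrary units, log axis) of the sort genes Mnx1 and Sox1 and of 8 selected markers, with 1 point per array and a dashed line at the detection level of 157.5. Mnx1 lies below the line on all 4 arrays, and Pou5f1 reaches 11188 on the array labelled HB9-GFP+.

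Across genes, the log2 signals of the array labelled HB9-GFP+ correlated most closely with those of the ES array, with a Pearson r of 0.947. Its r was 0.878 with the Sox1 array and 0.790 with the granule array. The other pairs gave 0.884 for ES and Sox1, 0.802 for ES and granule, and 0.896 for granule and Sox1. These correlations are over 18193 genes, which are not independent replicates, with values below the low level set to it, so that many genes share one value. Without that floor, over the genes detected on either array of a pair, the array labelled HB9-GFP+ had an r of 0.853 with ES, 0.667 with Sox1 and 0.467 with granule. By the rule of size, 242 genes were at least 4-fold higher on both the ES array and the array labelled HB9-GFP+ than on each of the other 2 arrays, and 285 genes were higher on both the granule and Sox1 arrays. The remaining ways of pairing the arrays gave 16 genes or fewer.

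**Figure D2:**
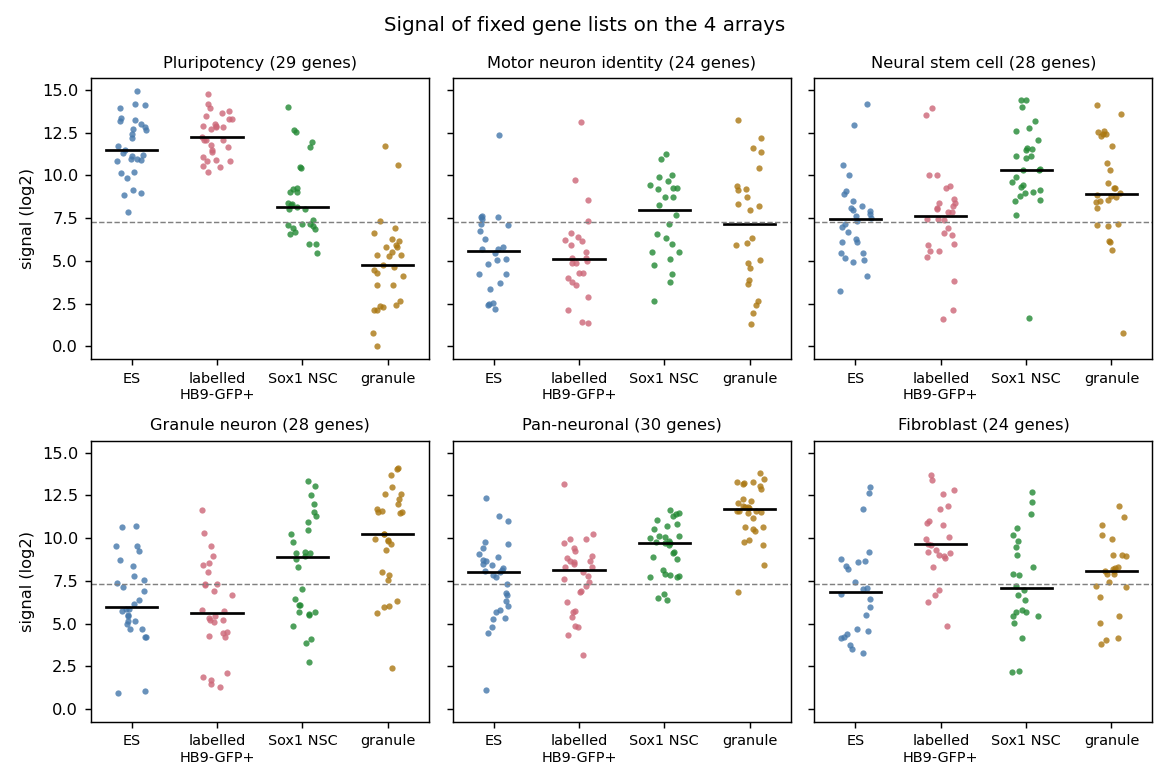
Log2 signal of the measured members of 6 gene lists on each array. Points are genes, black bars are medians, the dashed line is the detection level, and signals below 1 are drawn at 1. The median pluripotency signal was 4954.8 on the array labelled HB9-GFP+ and 2869.7 on the ES array.

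The first comparison set the array labelled HB9-GFP+ against undifferentiated ES cells. Part of the fibroblast list was higher on the array labelled HB9-GFP+, 28 of 29 pluripotency genes differed by less than 4-fold, and no pan-neuronal gene was called higher. Of 24 measured fibroblast genes, 9 were higher and 0 lower, with a median log2 difference of 1.44 that exceeded that of all matched random lists (percentile 100). The collagen gene Col3a1 had a signal of 6165.2 against 20.6 and was at least 78.3-fold higher, with a log2 difference of 2.78 on its other detected probe set, and the proteoglycan gene Dcn was at least 42.9-fold higher. Col1a2, a further collagen gene, was at 3696.3 against 134.4 and S100a4 was at least 21.7-fold higher, the latter at 1710.3 against 25.2. Of 29 pluripotency genes, 1 was higher and 0 lower, with a median of 0.54 (percentile 99.77). The higher gene was Dppa3, at 1153.5 against 231, while Utf1 stood at 1801.6 against 510.5 and Gdf3 at 1804.8 against 571.6, both short of 4-fold. Of 30 pan-neuronal genes, 0 were higher and 1 was lower, the intermediate filament gene Ina, at 387.9 against 2506.2.

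The lists of the motor neuron lineage showed few calls. In the motor neuron list 1 of 24 genes was higher, the guidance ligand Slit2, at 858.1 against 136.7. Among 15 ventral progenitor genes, 2 were higher, the basic helix-loop-helix factors Olig1 and Olig2. Olig1 was at 619.7 against 61.9, and Olig2, a determinant of motor neuron progenitors, was at 320.6 against 0.9. Among 15 motor column genes, 1 was lower, Epha4, at 691.2 against 3078.2, and among 24 genes of other spinal neurons 1 was lower, Tal2. No call was made among 11 cholinergic genes, 28 granule neuron genes, 12 Purkinje and interneuron genes, 13 genes of Hox paralogs 1 to 5, 20 of paralogs 6 to 13, 21 glutamate receptor genes, 17 GABA and glycine receptor genes or 24 voltage-gated channel genes. Of 28 neural stem cell genes, 2 were higher, Id3 (661.1 against 30.8) and Fgfr3 (329.4 against 76.2). The hedgehog list had 2 of 14 higher, Gas1 (2431.6 against 318.4) and the cyclin gene Ccnd1 (2892.9 against 572.7). The retinoic acid list had 1 of 19 lower, the germ cell gene Stra8 (1731.3 against 7962.3). Axon guidance genes were mixed, with 4 of 37 higher and 1 lower. The higher ones included Cxcl12 at 1389.8 against 58.2 and Ntn1 at 593.1 against 30.6.

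Early response and stress genes lay above matched random lists, with a median of 0.83 (percentile 100), but only 2 of 25 were called higher, Jun and Fos. Fos was at 3609.5 against 853.8. The cell cycle exit list also holds the cyclin genes Ccnd2 and Ccnd3, so its counts are not counts of exit genes alone. It had 1 of 16 higher, Ccnd2. The astrocyte list had 2 of 15 higher, Apoe and Fgfr3, and the oligodendrocyte list 1 of 13, Olig1. Trophic factor genes had 1 of 31 higher (Ptn) and 1 lower (Lifr, the receptor for leukemia inhibitory factor, at 1469.6 against 6517.4). Mesoderm and endoderm genes had 0 of 25 higher and 1 lower (Dab2), and DNA methylation regulators 0 of 11 higher and 1 lower (Tet2, at 848.5 against 4189.7). No call was made among 27 cell cycle genes, 20 vessel, blood and microglia genes, 12 neural crest and sensory genes, 18 BAF subunit genes or 18 glycolysis genes. Among 12 reference genes 1 was higher, Hprt, and among 6 sex-linked genes 1 was lower, Xist. The probe set that represents Xist was at 159.1 against 873.3. Its other probe sets were undetected on both arrays, at 1.1 against 31 and 24.3 against 29.2, so the call rests on 1 probe set.

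Over all genes, 202 were higher and 148 lower, together 3.46% of the 10117 genes detected on at least one of these arrays. The 8 largest differences were taken with low values set to the low level, so several are bounds and have no order among themselves. They included Hprt, a purine salvage enzyme gene measured by 1 probe set, which was at 8529.3 on the array labelled HB9-GFP+ and undetected at 90.3 on the ES array. With it stood Mgp, a matrix protein gene (at least 78.8-fold higher), Lcn2 and Saa3, which are acute-phase genes, and Bgn, a matrix proteoglycan gene. In the other direction they were Kbtbd11 (undetected at 123.7 against 3154.6), Mid1 (24.4-fold lower), St8sia1, Mfap3l, Clgn, Snhg11, Ttc14 and Slc27a2. The differences of the hybridisation controls had an SD of 0.11 log2 units, and those among the probe sets of a gene a pooled SD of 0.60. Of 108 called genes with at least 2 detected probe sets, 101 had the same sign in all of them. A further probe set fell short of 4-fold for St8sia1 (-1.88), Clgn (-1.54) and Ttc14 (-0.41). The share of calls that were higher was 57.7%, against 67.7% with quantile normalization and 19.0% with centring on reference genes (94 higher and 401 lower). That centring gave medians of 0.02 for pluripotency, 0.31 for early response and 0.92 for fibroblast genes, while without Hprt among the reference genes it gave 61.2% (197 higher and 125 lower) and medians of 0.57, 0.86 and 1.45. The mean over probe sets gave 0.63 for fibroblast genes.

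**Figure D3:**
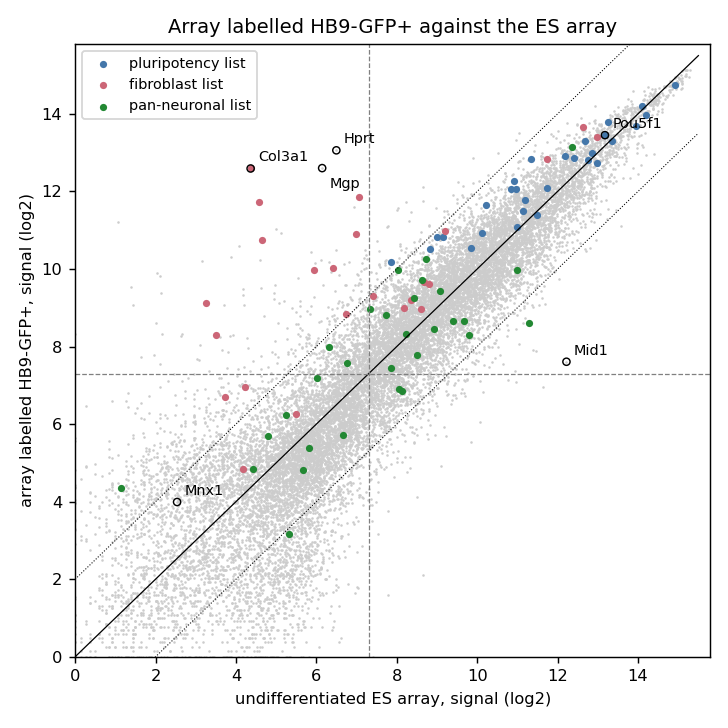
Log2 signal of 18193 genes on the array labelled HB9-GFP+ (vertical axis) against the ES array (horizontal axis), with members of 3 gene lists in colour. Solid and dotted lines mark equality and 4-fold differences, and dashed lines mark detection. Hprt (8529.3 against 90.3) and fibroblast genes such as Col3a1 lie far above the diagonal, while pluripotency genes lie near it.

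The comparison with the Sox1 array sets the array labelled HB9-GFP+ against neural stem cells. Pluripotency genes were higher on the array labelled HB9-GFP+ and many genes of neural stem cells, neurons and patterning were lower. Of 29 pluripotency genes, 24 were higher and 0 lower (median 4.44, percentile 100), among them Tdgf1, a Nodal co-receptor gene (71.6-fold), and Fbxo15 (7171.9 against 105). Of 28 neural stem cell genes, 16 were lower and 0 higher (median -2.62, percentile 0). Fabp7, the brain fatty acid binding protein of radial glia, was at 47.9 against 21466 and at least 273-fold lower, and Ednrb and Pax6 were also lower. Pan-neuronal genes had 2 of 30 higher and 13 lower (median -1.47), including Elavl4, Nefm and Map2, the last at 75.4 against 1068.3. The motor neuron list had 0 of 24 higher and 8 lower (median -1.03), and the lower ones included Neurod4 (13.3 against 1039.4), Ebf3, Onecut2 and the proneural gene Neurog2 (19.7 against 619.3).

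Several lists of patterning genes held more lower than higher members. Ventral progenitor genes had 2 of 15 higher and 8 lower (median -2.53). The higher ones were Olig1 (619.7 against 50.3) and Olig2 (320.6 against 78.2), both undetected on the Sox1 array. Among the lower ones, Irx3 was at 200 against 8508.8. Hox paralogs 1 to 5 had 0 of 13 higher and 6 lower, with Hoxb3 at 85 against 3626.3 and Hoxb1 at 25 against 2111.2, while no call was made among the 20 genes of paralogs 6 to 13. The hedgehog list had 0 of 14 higher and 6 lower, including the pathway's transducer Smo and its effector Gli3. The retinoic acid list had 1 of 19 higher and 8 lower, with the binding protein gene Crabp2 at 216.9 against 12979. Axon guidance genes had 1 of 37 higher and 15 lower, led by the ephrin receptor gene Epha7. Granule neuron genes had 0 of 28 higher and 9 lower (Zic1 at 44.3 against 8468.3), motor column genes 1 of 15 higher and 4 lower, trophic factor genes 0 of 31 higher and 4 lower, and mesoderm and endoderm genes 0 of 25 higher and 4 lower. The last 4 were Ttr (17.5 against 1062.6), Foxa2, which also marks the floor plate, Afp and Dab2.

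Fibroblast genes had 11 of 24 higher and 0 lower in this comparison (median 1.90, percentile 100), led by Col3a1 and Dcn. Early response and stress genes had 8 of 25 higher and 2 lower (median 1.15), with the stress-induced pseudokinase gene Trib3 at 977.8 against 82.7 and asparagine synthetase, Asns, at 11486 against 1803.1. Glycolysis genes had 3 of 18 higher and 0 lower (median 0.92), with the phosphofructokinase gene Pfkp at 10086 against 168.4. Its log2 difference was 5.904 on that probe set and 1.498 on its other one, which falls short of 4-fold. DNA methylation regulators had 2 of 11 higher and 0 lower, Dnmt3l at 5412 against 106.8 and Tet1. Cell cycle genes had no call among 27, with a median of 0.50 that was -0.18 with centring on reference genes. The smaller calls were astrocyte 2 higher and 1 lower of 15, oligodendrocyte 1 and 1 of 13, Purkinje and interneuron 1 and 1 of 12, cell cycle exit 0 and 2 of 16, neural crest and sensory 0 and 2 of 12, GABA and glycine receptor 0 and 2 of 17, and sex-linked 0 and 1 of 6 (Uty). The 2 lower members of the cell cycle exit list were Cdkn1c and the cyclin gene Ccnd2. A single gene was lower in each of the cholinergic (Chrna7), other spinal neuron (Prdm8), glutamate receptor (Grik3) and BAF lists (Smarce1). The reference list had 1 gene higher, Hprt, at 93 on the Sox1 array. Voltage-gated channel genes and vessel, blood and microglia genes had no call.

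Over all genes, 586 were higher and 723 lower, 12.5% of the 10496 detected. The 8 largest differences, with low values set to the low level, included those of Hprt (8529.3 against 93, undetected), Mgp and Col3a1 on one side, and on the other those of Fabp7, Zic1, Fndc3c1, Epha7, Ildr2, Pcdh8, Itgb8 and Prss23. The SD was 0.09 over hybridisation controls and 0.72 among probe sets of a gene, and 464 of 489 called genes with at least 2 detected probe sets had the same sign in all of them. A further probe set gave -1.37 for Ildr2, -2.77 for Epha7 and 2.78 for Col3a1. The share of higher calls, 44.8%, was 20.7% with centring on reference genes (338 higher and 1297 lower) and 38.7% without Hprt among them (498 and 789). With the mean over a gene's probe sets the medians shrank to 2.80 for pluripotency, -0.82 for neural stem cell, -0.38 for pan-neuronal, -0.15 for motor neuron and 1.05 for fibroblast genes, and 407 genes were lower.

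The comparison with the granule array sets the array labelled HB9-GFP+ against cells taken from the postnatal cerebellum, on whose array markers of glia and other neurons were also detected. All 29 measured pluripotency genes were higher (median 5.75, percentile 100), and 24 of 30 pan-neuronal genes were lower. Dppa5a was at 27366.6 against 79.1, Pou5f1 was at least 142-fold higher, and the cadherin gene of epithelial and ES cells, Cdh1, at least 148-fold higher. The pan-neuronal list had a median of -3.52 (percentile 0) and 1 member higher. Its lower members included the migrating-neuron microtubule gene Dcx, at least 122-fold lower on its brightest probe set but at -1.11 on another, Map2 and Rbfox3, which was at 115 against 11270. Granule neuron genes had 0 of 28 higher and 18 lower (median -2.97). The secreted guidance protein gene Reln was at 37.1 against 13182.7, at least 167-fold lower, and Zic1, a granule lineage factor, at least 224-fold lower.

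Among voltage-gated channel genes 0 of 24 were higher and 11 lower, among glutamate receptor genes 0 of 21 were higher and 7 lower, and among GABA and glycine receptor genes 0 of 17 were higher and 5 lower. Cacna2d1, a calcium channel subunit gene, was at 81.2 against 2967.8, and Gria4, an AMPA receptor gene, at 3.6 against 2251.2. Axon guidance genes had 0 of 37 higher and 14 lower, with the netrin receptor gene Dcc at 2.7 against 7475.4. Neural stem cell genes had 1 of 28 higher and 9 lower, motor neuron genes 0 of 24 and 7, motor column genes 2 of 15 and 4, other spinal neuron genes 0 of 24 and 4, ventral progenitor genes 0 of 15 and 3, hedgehog genes 1 of 14 and 3, trophic factor genes 0 of 31 and 9, and cholinergic genes 0 of 11 and 2. BAF subunit genes had 0 of 18 higher and 5 lower, including Smarca2 and the neuronal subunit gene Actl6b. The cell cycle exit list went both ways, with 3 of 16 higher, the cyclin gene Ccnd3 among them, and 4 lower, Ccnd2 among them. Retinoic acid genes did so too, with 3 of 19 higher and 2 lower.

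Some markers of other cerebellar cells were also lower on the array labelled HB9-GFP+ and were detected on the granule array. Astrocyte genes had 0 of 15 higher and 7 lower, with the water channel gene Aqp4 at 8741.8 and Gfap at 2224.6 on the granule array. Oligodendrocyte genes had 0 of 13 higher and 9 lower, with Gpr17, a gene of the precursors, at 2693.6 there. Purkinje and interneuron genes had 0 of 12 higher and 8 lower, with Pcp2 at 1954.4 and the GABA-synthesising enzyme gene Gad1 at 2507.3. Vessel, blood and microglia genes had 1 of 20 higher and 6 lower, with the microglial receptor gene Csf1r at 4072.5. These markers of other cells stand beside each neuronal list named above. Glycolysis genes had 9 of 18 higher and 0 lower (median 1.87, percentile 100), led by the glucose transporter gene Slc2a1 at 21184 against 726. Fibroblast genes had 9 of 24 higher and 0 lower, cell cycle genes 3 of 27 higher and 1 lower, and DNA methylation regulators 3 of 11 higher and 0 lower. One of these 3 was Dnmt3a, at 3252.3 against 65.4, a log2 difference of at least 5.37. The value was 1.28 with the mean over its probe sets. With quantile normalization, where the representing probe set is chosen again, it was -0.92. Early response and stress genes had 6 of 25 higher and 3 lower. Mesoderm and endoderm genes had 1 of 25 higher (Krt8), neural crest and sensory genes 0 of 12 higher and 2 lower, and sex-linked genes 0 of 6 higher and 2 lower (Xist and Kdm5d). Neither Hox list nor the 12 reference genes had a call.

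Over all genes, 1006 were higher and 1348 lower, 21.6% of the 10922 detected, and the median difference of genes detected on both arrays was 0.17. Besides the genes named above, Gpm6a, Gpm6b, Insm1 and Cadps2 were among the 8 largest lower differences, and Rhox5, Hspb1, Tdgf1, Dppa2 and Zfp42 among the 8 largest higher ones. The SD was 0.11 over hybridisation controls and 0.85 among probe sets of a gene, and 943 of 979 called genes with at least 2 detected probe sets had the same sign in all of them. A further probe set gave -3.27 for Gpm6b and -4.26 for Insm1. The share of higher calls, 42.7%, was 23.2% with centring on hybridisation controls (622 higher and 2061 lower), 18.1% on reference genes (489 and 2217) and 19.7% on those without Hprt (552 and 2245). With the mean over probe sets the fibroblast median was 0.67 and 865 genes were lower.

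The comparison of the Sox1 array with the ES array sets neural stem cells against undifferentiated cells. Most genes of the neural stem cell list were higher on the Sox1 array and most pluripotency genes lower. Of 28 neural stem cell genes, 18 were higher and 0 lower (median 2.91, percentile 100). Fabp7 was at 21466 against 43.7, at least 273-fold higher, and the neural cadherin gene Cdh2 at 9286.4 against 68.5, at least 118-fold higher, with a log2 difference of 3.19 on its other detected probe set. Of 29 pluripotency genes, 21 were lower and 0 higher (median -3.54, percentile 0), with Tdgf1 67.5-fold lower and Fbxo15 at 105 against 6857.6. The other 8 pluripotency genes did not pass the rule. Among them, Sox2, which neural progenitors also use, was at 16173 against 18877, Sall4 at 6334.6 against 6565.2, Trim71 at 3190.2 against 2320.8 and Lin28a at 6055.7 against 2006.4.

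Patterning lists held higher members. Hox paralogs 1 to 5 had 6 of 13 higher and 0 lower (median 1.77), including Hoxb1 (2111.2 against 46.6), Hoxa2 (2051.6 against 28.1), Hoxb2 (1051.6 against 42.8) and Hoxb3 (3626.3 against 2.9), while no gene of paralogs 6 to 13 was called among 20. Ventral progenitor genes had 9 of 15 higher and 0 lower (median 2.53), including Dbx1 at 1871.1 against 47.5. Olig1 (50.3 against 61.9) and Olig2 (78.2 against 0.9) were undetected on both arrays. The hedgehog list had 7 of 14 higher and 0 lower (median 2.17), with Gas1 at 7143 against 318.4. The retinoic acid list had 7 of 19 higher and 1 lower. Crabp2 was at 12979.2 against 92.2 and Stra8 at 90.3 against 7962.3. Axon guidance genes had 15 of 37 higher and 0 lower (median 1.52), and trophic factor genes 5 of 31 higher and 1 lower, with the heparin-binding factor gene Ptn at 15732 against 46.5. The log2 difference of Ptn was at least 7.64 on that probe set and as low as 1.14 on another.

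Pan-neuronal genes had 9 of 30 higher and 1 lower (median 1.11), with Elavl4 at 1675.1 against 100.9. The motor neuron list had 8 of 24 higher and 0 lower, including Slit2, Neurod4, Ebf3 and Onecut2, and the granule neuron list 8 of 28 higher and 0 lower, including Zic1 and Meis1. Motor column genes had 2 of 15 higher, BAF subunit genes 2 of 18 and the cell cycle exit list 3 of 16, each with 0 lower. The last 3 included the cyclin gene Ccnd2. Single genes were higher in the lists of other spinal neurons (Prdm8), Purkinje cells and interneurons (Foxp2), neural crest and sensory neurons (Tfap2b), glutamate receptors (Grik3) and GABA and glycine receptors (Glra1). No call was made among the cholinergic, oligodendrocyte, voltage-gated channel or reference genes. Glycolysis genes had 0 of 18 higher and 3 lower (median -0.87, percentile 0), with Pfkp at 168.4 against 7412.7, and DNA methylation regulators 0 of 11 higher and 3 lower, with Dnmt3l at 106.8 against 5822.8. Cell cycle genes had 1 of 27 lower, Ttk. Early response and stress genes had 4 of 25 higher and 4 lower, fibroblast genes 4 of 24 higher and 1 lower, astrocyte genes 2 of 15 higher and 2 lower, mesoderm and endoderm genes 3 of 25 higher and 1 lower, vessel, blood and microglia genes 0 of 20 higher and 1 lower, and sex-linked genes 0 of 6 higher and 1 lower. The mesoderm and endoderm genes that were higher included Ttr (1062.6 against 24.7), Foxa2 and Afp.

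Over all genes, 653 were higher and 549 lower, 11.4% of the 10532 detected. Nr2f1, Tox3 and Prss23 were also among the 8 largest higher differences, and Triml1, Fam25c, Icam1 and Mymx among the 8 largest lower ones. The SD was 0.07 over hybridisation controls and 0.56 among probe sets of a gene, and 439 of 442 called genes with at least 2 detected probe sets had the same sign in all of them. With the mean over probe sets the medians were 0.89 for neural stem cell and 0.37 for pan-neuronal genes, and 387 genes were higher.

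Genes set apart on 1 array were at least 4-fold above each other array, where some were still detected. Irx3 on the Sox1 array, for example, was at 8508.8, with 166.1 to 284.4 on the other 3. The granule array had 494 such genes, led by the water channel gene Aqp4, the matrix gene Sparcl1, Sphkap, Ppp1r14c, the nuclear factor genes Nfia and Nfib, Pcp4 and Cadps2. The Sox1 array had 112, led by Crabp2 (59.8-fold above the next array), Fndc3c1, Hoxb3, Sp8, Irx3, Prss23, Hoxb1 and Hoxa2. The array labelled HB9-GFP+ had 75, led by Mgp (at least 78.8-fold above the next array), Lcn2, Saa3, S100a4, the cyclooxygenase gene Ptgs2, Ifi27, the collagen cross-linking enzyme gene Lox and the growth factor gene Ereg. The ES array had 45, led by the lysine catabolism gene Aass (11.2-fold), Dpys, Fbp2 and Rbp7. Without the array labelled HB9-GFP+ the ES array had 431. The counts also depend on the scaling. Centring on reference genes gave 69 on the ES array and 38 on the array labelled HB9-GFP+, and without Hprt 29 and 60. Centring on hybridisation controls gave 863 on the granule array and 74 on the Sox1 array. Genes at least 4-fold below every other array numbered 158 on the granule array (led by Sall4 and Mtm1), 37 on the ES array (Timp2, Eef1akmt2), 25 on the array labelled HB9-GFP+ (Kbtbd11, St8sia1) and 21 on the Sox1 array (Cd9, Laptm5).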

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

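Probe sets without a gene name were outside every comparison of the report. They were examined by the same rule of size, with each probe set counted on its own. Of 9160 such probe sets that were not controls, 31 were at least 4-fold above the other 3 arrays on the ES array, 175 on the granule array, 8 on the array labelled HB9-GFP+ and 14 on the Sox1 array. What drew attention to them is signal in data that no comparison used. The order of the 4 arrays differs from that of the named genes, where the ES array had 45 and the array labelled HB9-GFP+ had 75. The numbers detected differed too. Of the unnamed probe sets, 1680 were detected on the ES array, 1940 on the granule array and 1460 on the Sox1 array. On the array labelled HB9-GFP+ 899 were detected, so its count of 8 comes from fewer detected probe sets. The probe set with the largest gap was at 8102.2 on the granule array, 4597.6 on the Sox1 array, 1671.1 on the array labelled HB9-GFP+ and 745.8 on the ES array, a different probe set in each case. No explanation was tested for these probe sets. With 1 sample per group, no group could be examined for outlying samples.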

How the results depend on the processing

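No paired analysis was possible because each group had 1 array, and for that reason no replicate could be left out. Over all alternatives, 127 values of the 12 counts stayed within 1.5 times and 44 moved, and of the list medians 1784 stayed, 63 moved and 1 reversed. Of the values for named genes, 6769 stayed, 425 moved and 1 reversed. For medians and genes, stayed means a shift below the comparison's SD among probe sets (0.60, 0.72, 0.85 and 0.56 log2 units), a wide tolerance for a median. Centring on the hybridisation controls, centring on reference genes without Hprt, and leaving out the array labelled HB9-GFP+ were added after the data were seen. Detection margins of 0 and 2 and pseudocounts of 1 and 16 moved no count, and the margins could not, since a 4-fold difference over the low level already passes them (setting: detection margin 2). Neither the margins nor the size thresholds can change a difference, so the 132 list medians and 517 named-gene values under each of those 4 settings stayed by construction.

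By construction a lower size threshold calls more genes. At 1 log2 unit, higher and lower counts were 1210 and 1279 for HB9-GFP+ minus ES, 2090 and 2099 minus Sox1, 2937 and 2904 minus granule, and 2004 and 2035 for Sox1 minus ES, with 396, 1278, 452 and 370 genes set apart on the ES, granule, HB9-GFP+ and Sox1 arrays. At 3 log2 units they were 51 and 11, 235 and 258, 369 and 622, and 271 and 173, with 1, 184, 25 and 42 set apart. The mean over a gene's probe sets includes dim probe sets and gave 407 genes lower against Sox1, 865 lower against granule and 387 higher for Sox1 minus ES. Its list medians were 0.63 for fibroblast genes against ES; 2.80 (pluripotency), -0.15 (motor neuron), -0.82 (neural stem cell), -0.38 (pan-neuronal) and 1.05 (fibroblast) against Sox1; 4.73, -2.64 and 0.67 (pluripotency, pan-neuronal, fibroblast) against granule; and -2.92, 0.89 and 0.37 (pluripotency, neural stem cell, pan-neuronal) for Sox1 minus ES. Without a floor, low values enter and the medians were 8.18 (pluripotency) and -1.36 (motor neuron) against granule and 1.42 (motor neuron) for Sox1 minus ES.

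As deposited, the median difference of genes detected on both arrays was 0.04 against ES, 0.05 against Sox1 and 0.17 against granule. For Sox1 minus ES it was -0.01. Centring on reference genes gave medians of -0.44, -0.57, -0.48 and 0.13 in the same order. It gave 94 higher and 401 lower against ES, 338 and 1297 against Sox1, 489 and 2217 against granule, and 69 and 38 genes set apart on the ES and HB9-GFP+ arrays, and it reversed the cell cycle median against Sox1 to -0.18. Hprt is 1 of the 12 reference genes. Without it the median difference was 0.07 against ES, -0.08 against Sox1 and -0.45 against granule. In the last comparison 552 genes were then higher and 2245 lower, with 29 and 865 set apart on the ES and granule arrays. Centring on hybridisation controls gave a median difference of -0.32 against granule, with 622 genes higher and 2061 lower. It gave 863 and 74 genes set apart on the granule and Sox1 arrays. With quantile normalization Dnmt3a against granule stood at -0.92. The probe set that represents a gene is chosen again under each scaling, and Dnmt3a has 5. Quantile normalization keeps the order of probe sets within an array. The probe set at 3252.3 against 65.4 lay above the median signal of the array labelled HB9-GFP+, 61.9. It lay below that of the granule array, 90.7, so it could not become lower. The value of -0.92 therefore comes from another probe set. The direction for Dnmt3a depends on the probe set, and the change cannot be read as an effect of normalization on 1 probe set. Without the array labelled HB9-GFP+, 431 genes were set apart on the ES array, since the array most like it was gone. Signal over background limits the lower calls: genes near the low level of 78.8 have only bounds.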

Other observations

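All tests in this part were chosen after the results were seen, and the criteria for the feeder source and for the Hprt probe set were changed once more after a first version had been run. On the Sox1 array 18 of the 29 pluripotency genes were still detected. Pou5f1 was at 514.3 and Nanog at 324.3 there, both above the detection level, against 21.7 and 4.4 on the granule array. The 16 genes at least 4-fold higher on both the granule array and the array labelled HB9-GFP+ than on the other 2 included matrix genes (Col3a1, Dcn, Bgn), the chemokine gene Cxcl12, the glial factors Olig1 and Olig2, Tnc, Apoe and Hprt. Of these 16, 2 were in the fibroblast list. Only 2 genes showed the opposite pairing, Epha4 and Sulf1.

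The profile of the array labelled HB9-GFP+ was weighed first. An exchange of labels among these arrays, as the source of this profile, would leave another array without the profile of its own label, and 0 of the other 3 lacked it, although an exchange between the array labelled HB9-GFP+ and the ES array, which share the profile, would not show here, would not account for the profile, and would turn every direction between them. Neurons that had kept pluripotency transcripts, if as rich in neuronal transcripts as the granule cell array, would lie near its level. The pan-neuronal median lay at -3.52 log2 units from that array. Neurons with lower levels than postnatal cells are not excluded by this value. Against the ES array, 0 of 30 pan-neuronal genes were higher. RNA mainly from undifferentiated cells, through a single wrong label or a sort that did not exclude them, is consistent with a pluripotency median 0.54 log2 units from the ES array, and it remains a hypothesis because it was found on the same values. Olig1 and Olig2, at 619.7 and 320.6, were at 61.9 and 0.9 on the ES array, so an added minority of differentiating cells stays open.

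The fibroblast genes on the array labelled HB9-GFP+ were weighed next. Feeder fibroblasts in the sample stay open as a source, since the reporter line was kept on them, but the 9 of 24 fibroblast genes higher than on the ES array only restate the pattern and do not favour feeders over another source. Lgals1, Fn1 and Sparc, at 13041, 10805 and 7242.1, were not called against the ES array (6339.3, 8058.9 and 3395.3), while Col3a1 was at 6165.2 against 20.6; 10 of the 24 genes were detected on the ES array and 0 belong to another of the lists. Cells that had entered early mesoderm or endoderm would raise the genes of that list, and 0 of 25 were 4-fold higher. Only 8 of the 25 were detected on the brighter of the arrays compared. The count cannot exclude a minority of such cells, or cells derived from them that no longer carry these markers. A working sort for GFP would be expected to remove feeder cells that carry no reporter. Whether this sample passed such a sort is itself in question, so this does not decide on the feeders.

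Hprt was low on both the ES and Sox1 arrays, at 90.3 and 93, and high on the other 2. A faulty probe set is argued against by its detection on 2 of the 4 arrays, at 8529.3 and 3348.8. Feeder fibroblasts may contribute to the log2 difference of Hprt between the array labelled HB9-GFP+ and the ES array, computed as 6.56. Its size is uncertain, because the ES signal of 90.3 is below detection. That difference exceeds the fibroblast list's median of 1.44, which the expectation stated for this source did not allow, but the median is a weak bound for a single gene, since Dcn of that list differed by at least 5.42 and Col3a1 by at least 6.29 on 1 probe set and 2.78 on the other, and no array of feeder cells was analysed here. Different parent lines are a further possibility: some widely used mouse ES lines lack Hprt, and the signal of 90.3 on the ES array, below detection, would fit a parent line shared with the Sox1 cells, but the labels used here give no genotype.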
